A study of Mus musculus with 2 samples.

How the data were processed

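Single-cell RNA was measured with the 10x Genomics Chromium platform in mouse embryonic brain tissue, in 1 library of the NTD group and 1 library of the control group. The deposited values were raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 7.0.1 per the file headers. The submitters' processing notes also name STAR and the mm10 genome build. The gene annotation, the intron setting and the cell-calling options are not given in the sources used here. The values were whole numbers of at least 1, and no deposited file gave cell types.

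Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, a filter that removed no barcode of the 18572 in the control library or the 19056 in the NTD library. Scrublet, run per library in scanpy 1.11.5 with its automatic threshold, called 3042 control barcodes (16.4%) and 2399 NTD barcodes (12.6%) doublets, and these were removed. The kept cells numbered 15530 with 38625058 UMIs in the control library and 16657 with 46827092 UMIs in the NTD library. The median per kept cell was 2167 UMIs in the control library and 2434 UMIs in the NTD library. The lowest UMI total of a barcode was 1027 in the control library and 1589 in the NTD library.

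Both libraries were clustered together without integration, from counts scaled to 10000 per cell and log transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1.0. This gave 24 clusters. A cluster was named X-like from markers of 25 classes chosen before the data were examined. The scoring rule was set after the clusters were seen. A marker counted when at least 10% of the cluster's cells held it and its mean was at least 1.25-fold that of the other cells. A name needed at least 3 such markers, a lead of 2 over the next class, and no more markers of another class than of its own among the 10 genes with the highest fold. By this rule 19 clusters took 10 class names and 5 clusters stayed unnamed. Differences from class names used elsewhere may come from these rebuilt names.

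Raw UMI counts were summed over the cells of a class in each library and scaled to CPM of that sum. The comparison was the log2 ratio of NTD over control, with 0.5 counts added. Only genes with at least 20 UMIs over both libraries in the class were measured. Because each group had 1 library, no test across samples existed, so no p-value and no count of changed genes was computed. CPM values have exact Poisson intervals and their ratios exact conditional binomial intervals. Shares of cells have exact Clopper-Pearson intervals, and differences of shares have Newcombe intervals. All are 95% intervals and cover counting error only.

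Gene lists, 40 in number, were also chosen before the data were examined. For each list the median log2 ratio of its measured members was computed, with a 95% interval from 1000 Poisson resamplings. Its percentile was taken among 10000 random lists of the same size matched on mean CPM in 20 bins. Members at least 1.25-fold higher or lower were counted as description. The genes to be named were fixed by a rule written at the same time. It took Alkbh1 and the other candidate enzymes of DNA N6-methyladenine. In the neural progenitor-like and in the neuron-like cells it took the 10 genes with the highest and the 10 with the lowest log2 ratio among genes of at least 50 CPM in either library. It took the 5 highest and 5 lowest over all kept cells, and from each list up to 3 members of at least 20 CPM with the largest absolute log2 ratio in neural progenitor-like cells. Haemoglobin genes, mitochondrial genome genes and predicted gene models were left out of the naming by size. Other genes named in the text were chosen after their values were seen, and the text says so where they appear.

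Cell cycle phases and shares of cells with a UMI of sex-linked genes were computed after each cell was thinned to 1559 UMIs, which left out 3876 control cells and 0 NTD cells. Gene coordinates and spans came from the GENCODE M21 annotation of GRCm38, matched on gene ID for 32235 of 32285 genes (99.8%). That annotation may differ from the one the authors used.

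The counting method was tested on simulated data for the neural progenitor-like class, with 16164 measured genes. For simulated log2 ratios of -2, -1, 1 and 2 the medians recovered were -1.97, -1.00, 0.99 and 2.00. The intervals of genes simulated without a difference held 0 for 95.8% of them. All 20 genes named by the size rule were ones simulated as changed, and 5.0% of 200 lists without a difference fell outside the central 95% of random lists. Both simulated libraries were Poisson counts drawn from a shared profile, with no dependence of ratios on genomic span. The simulation thus checks the counting steps only, and does not show that list percentiles hold in the real data.

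Alternatives tried were no cell filter, a stricter filter (at least 1000 genes and 2000 UMIs, at most 5% mitochondrial UMIs), doublets kept, Leiden resolutions 0.5 and 2.0, and genes scaled within each library before clustering. Further ones were TMM scaling, totals without mitochondrial, ribosomal protein and haemoglobin genes, thinned cells, cells weighted equally, members of at least 100 UMIs, and no thinning. Those added after the data were seen were a matched floor of 1589 UMIs, doublets removed at the expected rate, clusters weighted equally, Y-positive cells only, shares without clusters that took over 90% of their cells from 1 library, shares among neural cells only, and ratios relative to genes of like genomic span. The analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors only. Bulk RNA sequencing and cultured cells mentioned in the labels were not analysed here.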

Results

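Gene expression was profiled cell by cell in brain tissue of mouse embryos, with 1 library from embryos with neural tube defects (NTD) and 1 library from control embryos. The NTD embryos came from dams on a low-folate diet given 1.5 mg/kg of the folate antagonist methotrexate into the peritoneum on gestational day 7.5, and the control dams received normal saline. Neural tube closure was scored between embryonic days 9.5 and 10.5, and the stage, number and sex of the embryos in each library are not given in the sources used here. The control library held 18572 barcodes with 50741121 UMIs and a median of 2234 UMIs per barcode. The NTD library held 19056 barcodes with 55524355 UMIs and a median of 2456 UMIs per barcode. There were no replicates, so no difference between the groups has a replicate check, and all intervals cover counting error only.

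The comparison of cell classes asked how the make-up of the tissue differed between NTD and control embryos. Neural progenitor-like cells, the dividing cells of the neural tube wall, made up 16.2% of kept control cells (15.6 to 16.8%) and 32.6% of kept NTD cells (31.9 to 33.4%), a 2.02-fold higher share. The clusters of this class went both ways. Cluster 6 held 7.22% of control and 3.91% of NTD kept cells, while cluster 1 held 4.11% and 14.8%, cluster 5 held 2.92% and 8.74%, and cluster 11 held 1.93% and 5.21%. Neuron-like cells made up 9.68% (9.22 to 10.2%) in the control library and 14.6% (14.1 to 15.2%) in the NTD library. Mesenchyme or fibroblast-like cells were lower in the NTD library, at 13.2% (12.7 to 13.7%) against 23.2% (22.6 to 23.9%). Muscle-like cells were also lower in the NTD library, at 0.468% against 2.65% of kept cells. Over all kept cells, the limb genes Tbx4 and Tbx5, chosen after their values were seen, were far lower in the NTD library, with Tbx4 at 14.4 CPM in control and 0.747 CPM in NTD and Tbx5 at 14.8 and 1.49 CPM. Cells of such tissue in only the control library would alter every share given here.

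Endothelial-like cells were 3.19% in the control library and 1.89% in the NTD library, and macrophage or microglia-like cells were 1.04% and 0.486%. Neural crest or Schwann precursor-like cells were 2.05% in the control library and 1.24% in the NTD library, and erythroid-like cells were 1.42% and 0.937%. Epithelium-like cells were 3.68% and 3.97%, a difference of 0.285 percentage points that was not detectable at this depth (-0.135 to 0.704). Neuroblast or intermediate progenitor-like cells were 4.73% in the control library and 4.03% in the NTD library, but this difference of -0.692 points turned to 0.755 when called doublets were kept and to 0.651 with the stricter cell filter. Clusters left unnamed held 32.2% of control cells and 26.5% of NTD cells. Among them, cluster 0, the largest, held 17.8% of control and 15.5% of NTD kept cells. It carried 8 erythroid and 7 neuron markers, with a median of 1126 UMIs in control and 1731.5 in NTD. It is taken below as nearest to free RNA, so some barcodes counted in every share may not be cells. Cluster 2, which carried mesenchyme markers, held 11.3% and 6.53%, cluster 13 held 1.89% and 3.10%, and cluster 20 held 0.232% and 1.38%. Cluster 22, with 6 markers of trophoblast, yolk sac or liver, held 0.947% and 0.0120%.

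Mesenchyme-like cells came mostly from clusters 7 and 8 in the control library, with 10.8% and 9.04% of kept cells, against 0.294% and 0.522% of NTD cells. The mesenchyme-like class held 458 of the 555 control UMIs of Tbx4 and 424 of the 573 of Tbx5, both chosen after their values were seen, so in the control library it was not connective tissue of the head alone. In the NTD library its cells came mostly from cluster 3, with 12.4% of kept cells against 3.41% of control cells. Clusters 7, 8, 17 and 22 took over 90% of their cells from the control library. Cluster 7 carried 7 and cluster 8 carried 8 mesenchyme markers. Cluster 17 carried 9 muscle markers, and cluster 22 carried 6 markers of the trophoblast, yolk sac or liver class. Leaving out these clusters therefore takes out cell types and is not a correction for library. Without them the mesenchyme-like share was 8.05 points higher in the NTD library. The muscle-like difference was then not detectable, at -0.0731 points (-0.228 to 0.0702), and the epithelium-like difference was -0.782 points. The neural progenitor-like share stayed 11.9 points higher and the neuron-like share 2.18 points higher in the NTD library. Among neural cells alone the neuron-like share was lower in the NTD library, with a difference of -3.15 points for NTD minus control. The lowest barcode total was 1027 UMIs in the control library and 1589 in the NTD library, and with a matched floor the neuron-like share was 2.64 points higher in the NTD library. With that floor the erythroid-like difference was not detectable, at -0.109 points (-0.353 to 0.123).

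**Figure D1:**
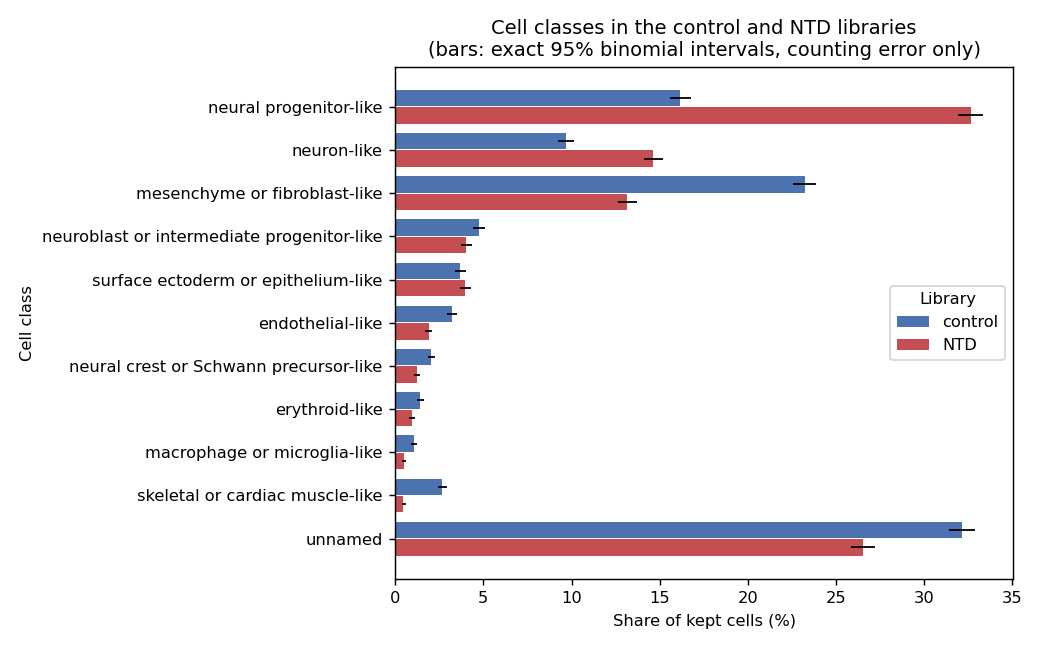
Share of kept cells (%, x axis) in each cell class (y axis) for the control and NTD libraries, with exact 95% binomial intervals for counting error only. Neural progenitor-like cells held 16.2% of control and 32.6% of NTD cells, and the mesenchyme-like share of 23.2% against 13.2% turned the other way without the clusters of 1 library.

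Genes of position along the head-to-tail axis were among those with the largest ratios in neural progenitor-like cells, in neuron-like cells and over all kept cells. In neural progenitor-like cells Hoxc6, which marks the trunk, was at 68.5 CPM in the control library (62.3 to 75.1) and 0.758 CPM in the NTD library (0.391 to 1.32), a log2 ratio of -6.44 (-7.46 to -5.68). All 23 measured posterior Hox genes (groups 4 to 13) were lower in the NTD library by the minimum fold used to count list members. Their median log2 ratio was -5.15 (-5.44 to -4.83), below all 10000 matched random lists. Of 16 measured forebrain genes, 11 were higher and 0 lower in the NTD library, with a median of 0.91 (0.65 to 1.10). Nkx2-1 had a log2 ratio of 1.46 (1.13 to 1.81), Six3 of 1.39 (1.08 to 1.73) and Lhx2 of 0.76 (0.58 to 0.96).

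Of 13 measured hindbrain genes, 9 were lower and 2 higher in the NTD library, with a median of -0.65 (-1.06 to -0.41). The 8 measured ones other than Hox genes had a median of -0.29 (-0.61 to 0.06), with an interval that held 0. Hoxa3 was at 107 CPM against 2.97 CPM, Hoxb3 at 140 against 8.14 CPM and Hoxb2 at 21.9 against 10.1 CPM. Midbrain and isthmus genes went both ways around a median of -0.12, which was 0.06 with TMM scaling. Among them Pax7 was lower, with a log2 ratio of -0.93 (-1.09 to -0.76), and Fgf8 higher, with 0.74 (0.44 to 1.06). The genes Hoxd4, Hoxb6, Hoxc4, Hoxb4 and the Hox antisense transcripts Hoxd3os1 and Hoxaas3 were among the 10 lowest by the size rule, with log2 ratios from -5.81 to -4.41.

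Also among the 10 lowest, with log2 ratios of -5.62 (-6.08 to -5.22) and -5.26 (-5.87 to -4.75), were Afp and Apoa1. Both are markers of the trophoblast, yolk sac or liver class. Together with Apoa2, added after its values were seen, they held between 0.0258 and 0.0343% of UMIs in each of the 10 named control classes, and at most 0.00147% in each NTD class. Free RNA gives such a like share in every class. Over all kept cells Afp was at 237 CPM in the control library and 3.63 CPM in the NTD library, a log2 ratio of -6.03. The other lowest genes there were Hoxc6 at -5.57, Apoa1 at -5.46, Hoxa9 at -5.07 and Hoxb6 at -4.78. Over all kept cells, 22 of 24 non-Hox genes of liver or yolk sac, limb, kidney, heart and somites were lower in the NTD library. They were listed after some of their values were seen. Of the 24, Ttr of the choroid plexus and Uncx are also expressed in brain, and Uncx was not lower, at -0.06 (-0.18 to 0.07). For the 12 of them not seen before listing, the median log2 ratio was -2.40 (-2.55 to -2.21). The labels give brain as the source of both libraries.

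**Figure D2:**
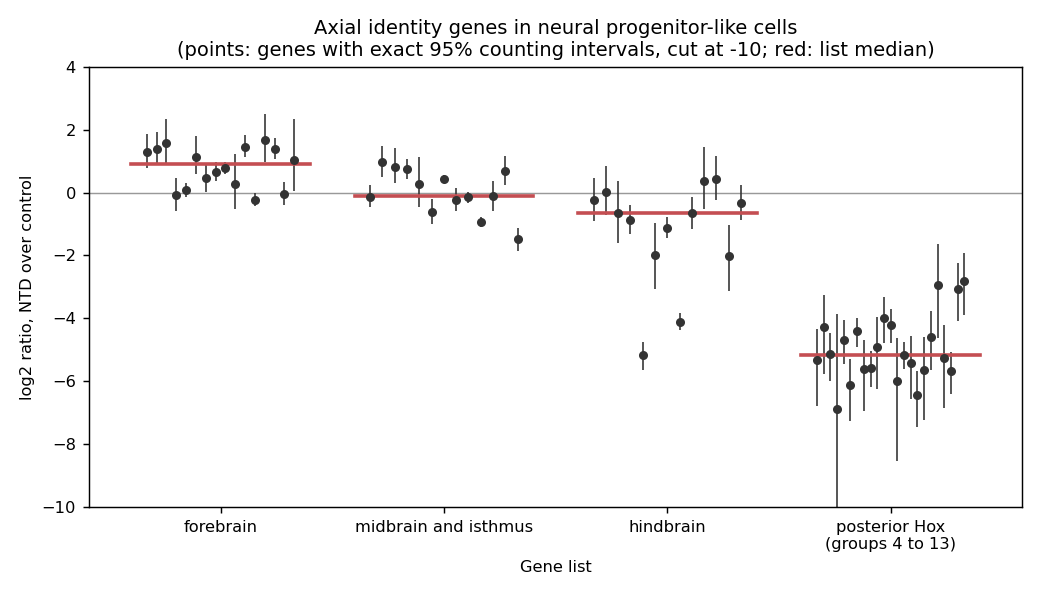
Log2 ratio of NTD over control (y axis) for genes of 4 axial lists (x axis) in neural progenitor-like cells, as points with exact 95% counting intervals and a red line at each list median. Forebrain genes had a median of 0.91 and posterior Hox genes of -5.15, and the midbrain median of -0.12 was positive with TMM scaling.

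The comparison within neural progenitor-like cells asked how Alkbh1, the enzyme in the study's title, and genes of DNA and histone methylation differed between NTD and control embryos. Alkbh1 (ENSMUSG00000079036), an AlkB family dioxygenase, lies on chromosome 12 from 87425840 to 87444017 in GRCm38. It was lower in the NTD library, at 132 CPM (127 to 138) from 2098 UMIs against 192 CPM (182 to 203) from 1257 UMIs in the control library. The log2 ratio was -0.54 (-0.64 to -0.43), a level 1.45-fold higher in the control library. Over all kept cells Alkbh1 was at 117 CPM in the NTD library and 176 CPM in the control library. It was lower in the NTD library in all 16 clusters with at least 100 cells in each library, by log2 ratios from -0.86 to -0.17, and in 15 of them the interval lay below 0. These clusters come from the same libraries and are not replicates. They include cluster 0, the low-UMI cluster taken as nearest to free RNA. There Alkbh1 was at 51.9 CPM in control and 30.4 CPM in NTD, a log2 ratio of -0.77 (-1.09 to -0.45).

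The other candidate enzymes of DNA N6-methyladenine were measured at lower levels. N6amt1 had a log2 ratio of -0.06 (-0.29 to 0.18) and Mettl4 of -0.12 (-0.41 to 0.18), both positive with TMM scaling, and Alkbh4, with 23 and 62 UMIs, had 0.14 (-0.56 to 0.91). No difference was detectable for these 3 genes at this depth. Of the 4 progenitor-like clusters, cluster 6 held the most cells in the control library and cluster 1 in the NTD library, with 7.22% and 14.8% of kept cells. Within the 4 progenitor-like clusters the Alkbh1 log2 ratio ranged from -0.76 to -0.30.

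The median log2 ratio of all 16180 measured genes in these cells was -0.19 with scaling by totals and -0.00 with TMM scaling, and over all kept cells it was -0.24 and -0.01. Alkbh1 had a log2 ratio of -0.35 with TMM scaling and of -0.40 (-0.50 to -0.29) relative to genes of like genomic span. Ribosomal protein genes took 8.15% of progenitor-like UMIs in the control library and 12.5% in the NTD library.

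**Figure D3:**
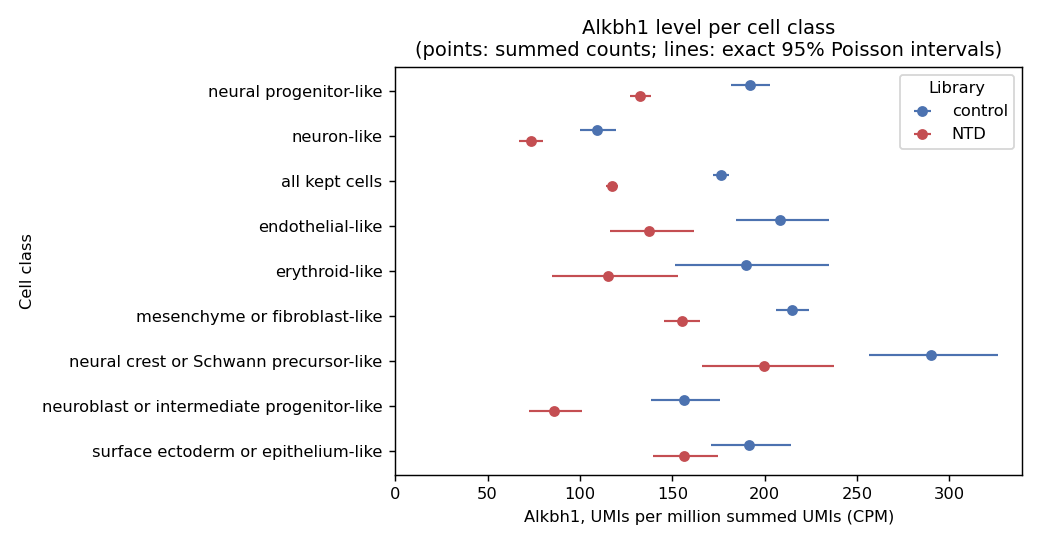
Alkbh1 level in CPM of summed UMIs (x axis) per cell class (y axis) in the control and NTD libraries, with exact 95% Poisson intervals. Alkbh1 was at 192 CPM in control and 132 CPM in NTD neural progenitor-like cells, and at 109 and 73.3 CPM in neuron-like cells.

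Genes of H3K9 methylation and heterochromatin lay near the shift of all genes. Their median was -0.18 (-0.23 to -0.08) by totals, 0.01 with TMM scaling and 0.03 relative to genes of like span. Of 25 measured members, 2 were lower and 0 higher in the NTD library by the same minimum. Smchd1, which acts on the inactive X chromosome, had -0.39 (-0.47 to -0.30), which was -0.20 with TMM scaling and -0.08 relative to genes of like span, and Cdyl, a reader of H3K9 methylation, had -0.34 (-0.48 to -0.19), which was 0.01 relative to like span. The 11 H3K9 demethylases had a median of -0.16 by totals and 0.03 with TMM scaling. The 12 genes of the 5-methylcytosine machinery had a median of -0.21 by totals and 0.06 relative to like span. Among them Mbd1 had -0.66 (-0.92 to -0.39) and the maintenance methyltransferase Dnmt1 had 0.27 (0.13 to 0.42). The 16 AlkB family and RNA m6A genes had a median of -0.06 by totals and 0.12 with TMM scaling.

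Folate and one-carbon genes had a median of -0.11 (-0.25 to -0.06) by totals and 0.07 with TMM scaling, with 8 of 28 members lower and 0 higher in the NTD library. The mitochondrial formate enzyme gene Mthfd1l was at 68.7 CPM against 104 CPM in control, a log2 ratio of -0.60 (-0.74 to -0.46), which was -0.26 relative to like span. Mat2a, which makes S-adenosylmethionine, had -0.35 (-0.42 to -0.27), which was -0.17 with TMM scaling, and Gldc had -0.21 (-0.39 to -0.03), which was 0.07 relative to like span. Purine and pyrimidine synthesis genes had a median of 0.08 by totals, 0.26 with TMM scaling and 0.23 relative to like span, with 3 of 23 higher and 1 lower. Dut, which removes dUTP, was at 402 CPM against 255 CPM in control, a log2 ratio of 0.66 (0.58 to 0.74).

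The p53 targets had a median of 0.01 (-0.11 to 0.15) by totals, which was negative in thinned cells, 0.20 with TMM scaling and 0.10 relative to like span, at the 98.7th percentile of matched lists, with 4 of 24 lower and 3 higher. Rrm2b had 0.60 (0.27 to 0.94) and Bax 0.31 (0.21 to 0.42), which was 0.49 with TMM scaling for Bax. Sesn1 had -0.26 (-0.43 to -0.09), which was 0.04 relative to like span. The apoptosis machinery had a median of -0.08 by totals and 0.11 with TMM scaling. The S phase genes had a median of 0.01 by totals, negative in thinned cells, 0.19 with TMM scaling and 0.15 relative to like span, at the 98.9th percentile, and G2 and M phase genes one of -0.05 by totals and 0.14 with TMM scaling. Of 43 S phase genes 3 were lower and 5 higher, and of 54 G2 and M phase genes 6 were lower and 6 higher. In these lists Pcna had 0.65 (0.55 to 0.74), Hmgb2 0.73 (0.68 to 0.78) and Ube2c 0.69 (0.61 to 0.77).

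Genes whose loss gives neural tube defects in mice had a median of -0.23 (-0.27 to -0.17) by totals and 0.02 relative to like span, with 15 of 45 lower and 7 higher in the NTD library. Pax3, which is needed for closure of the neural tube, was at 311 CPM in the NTD library and 589 CPM in control, a log2 ratio of -0.92 (-0.98 to -0.86). Of progenitor-like cells, 826 of 2512 in control and 4759 of 5438 in NTD held no Hox UMI. Part of this gap may be free RNA, since posterior Hox genes were also lower in NTD cells of cluster 0, at a median log2 ratio of -3.68. Forebrain genes were higher in NTD progenitor-like cells, at a median of 0.91. Position along the axis thus appears to have differed too, and it was not held fixed for Pax3 or the other genes here. Vcl, an adhesion gene, had -0.87 (-1.05 to -0.69), and the head mesenchyme gene Alx1 had 1.37 (1.01 to 1.77). Alx1 took a like share of UMIs in both neural classes, with 0.00104% of control and 0.00270% of NTD UMIs in progenitor-like and 0.00101% and 0.00279% in neuron-like cells, as free RNA gives. Planar cell polarity genes had a median of -0.34 (-0.46 to -0.28) by totals and -0.16 with TMM scaling, at the 2.65th percentile of matched lists, with 8 of 16 lower and 1 higher. Ror2 had -1.09 (-1.24 to -0.95), Prickle1 -1.06 (-1.24 to -0.87) and Celsr1 -0.76 (-0.95 to -0.57).

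Wnt pathway readouts had a median of -0.48 (-0.63 to -0.37) by totals and -0.29 with TMM scaling, with 9 of 13 lower and 1 higher in the NTD library. Wnt1 of the dorsal midline had -1.49 (-1.86 to -1.12), Lgr5 -0.64 (-0.86 to -0.41) and Axin2 -0.61 (-0.81 to -0.40). Hedgehog pathway genes had a median of -0.20 by totals and 0.05 relative to like span, with 4 of 16 lower and 5 higher. The receptor genes Cdon and Boc were at -0.70 (-0.79 to -0.60) and -0.54 (-0.63 to -0.45), Gli2 was at -0.39 (-0.49 to -0.29), and the ventral genes Shh, Olig2 and Nkx2-2, chosen after their values were seen, were at 1.06 (0.65 to 1.51), 0.83 (0.37 to 1.35) and 0.83 (0.32 to 1.41). Notch pathway genes had a median of 0.08 (-0.06 to 0.23) by totals and 0.26 with TMM scaling, with 4 of 16 lower and 6 higher. Nrarp was at 0.70 (0.47 to 0.95), Hes5 at 0.52 (0.44 to 0.61) and Mfng at 0.49 (0.22 to 0.76), and Jag2 and Notch1, chosen after their values were seen, were at -0.87 (-1.54 to -0.16) and -0.48 (-0.62 to -0.34). Of 13 retinoic acid pathway genes 7 were lower and 4 higher, with a median of -0.62 (-0.86 to -0.12) by totals and -0.34 relative to like span. The receptor gene Rarb was at 25.6 CPM against 229 CPM in control, a log2 ratio of -3.16 (-3.32 to -3.00), Dhrs3 had -2.63 (-3.07 to -2.22) and Crabp1 0.94 (0.86 to 1.02). The difference in position along the axis was not held fixed for any of these pathway genes, so the ratios cannot be told apart from it.

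Neuronal differentiation genes had a median of 0.27 (0.19 to 0.37) by totals, 0.45 with TMM scaling, 0.54 relative to like span, 0.12 with doublets at the expected rate and 0.13 with clusters weighted equally, with 14 of 31 higher and 3 lower in NTD progenitor-like cells. Stmn2 had 0.96 (0.84 to 1.08) and Stmn3 0.89 (0.75 to 1.05). These transcripts were also a larger part of UMIs in the NTD library in cells that should lack them, at 0.336% against 0.213% in macrophage or microglia-like cells and 0.410% against 0.286% in erythroid-like cells. Early-stage neuroepithelium genes had a median of 0.02 by totals, negative in thinned cells and 0.20 with TMM scaling, and late-stage progenitor genes one of -0.12 by totals and 0.06 with TMM scaling. Among the latter Fabp7, a lipid-binding protein of radial glia, was at 412 CPM against 182 CPM in control, a log2 ratio of 1.18 (1.09 to 1.27). The other genes highest by the size rule were Lmo1 at 1.12, Xist, Tsix and the histone genes Hist1h2ae at 1.57, Hist2h2ac at 1.43, Hist1h3c at 1.34, Hist1h1b at 1.27, Hist1h1e at 1.16 and Hist3h2ba at 1.15.

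Nuclear genes of oxidative phosphorylation had a median of 0.53 (0.46 to 0.54), with 17 of 26 higher and 0 lower in the NTD library, and Ndufa2 among them had 0.73 (0.62 to 0.84). Genes of the mitochondrial genome had a median of -0.65 (-0.72 to -0.53), with 11 of 13 lower and 0 higher, and mt-Cytb among them had -0.90 (-0.99 to -0.81). Hypoxia and glycolysis genes had a median of 0.15 (0.09 to 0.25) by totals and 0.33 with TMM scaling, with Gapdh at 0.64 (0.60 to 0.67). Heat shock genes had a median of 0.40 (0.31 to 0.47), with 6 of 10 higher and 0 lower, and Hspe1 at 0.60 (0.54 to 0.66). The integrated stress and unfolded protein response had a median of 0.20 (0.09 to 0.26) by totals and 0.38 with TMM scaling, and immediate early genes of dissociation one of 0.17 (0.01 to 0.33) by totals, 0.35 with TMM scaling and 0.11 relative to like span. Polyadenylated core histone variants had a median of 0.53 (0.42 to 0.56), with H2afz at 0.61 (0.58 to 0.64). Extracellular matrix genes had a median of -0.54 (-0.68 to -0.44) by totals and -0.23 relative to like span, with 14 of 20 lower and 0 higher, and Col1a1 at -1.42 (-1.62 to -1.21). Over all kept cells that list was lower too, at -0.69 with 19 of 20 members lower, and in cells that should lack most of it, it took 0.0985% of control and 0.0774% of NTD UMIs in erythroid-like cells and 0.0915% and 0.103% in macrophage or microglia-like cells. None of these 8 list directions turned under the scalings tried, but no scaling corrected for free RNA. Across genes the log2 ratio correlated at -0.770 with the level in progenitor-like cells over cluster 0, which shares control counts with the ratio. Mitochondrial UMIs were also lower in NTD cells of cluster 0, at 0.325% against 0.639% in control. The scalings therefore do not tell these directions apart from a difference in free RNA.

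**Figure D4:**
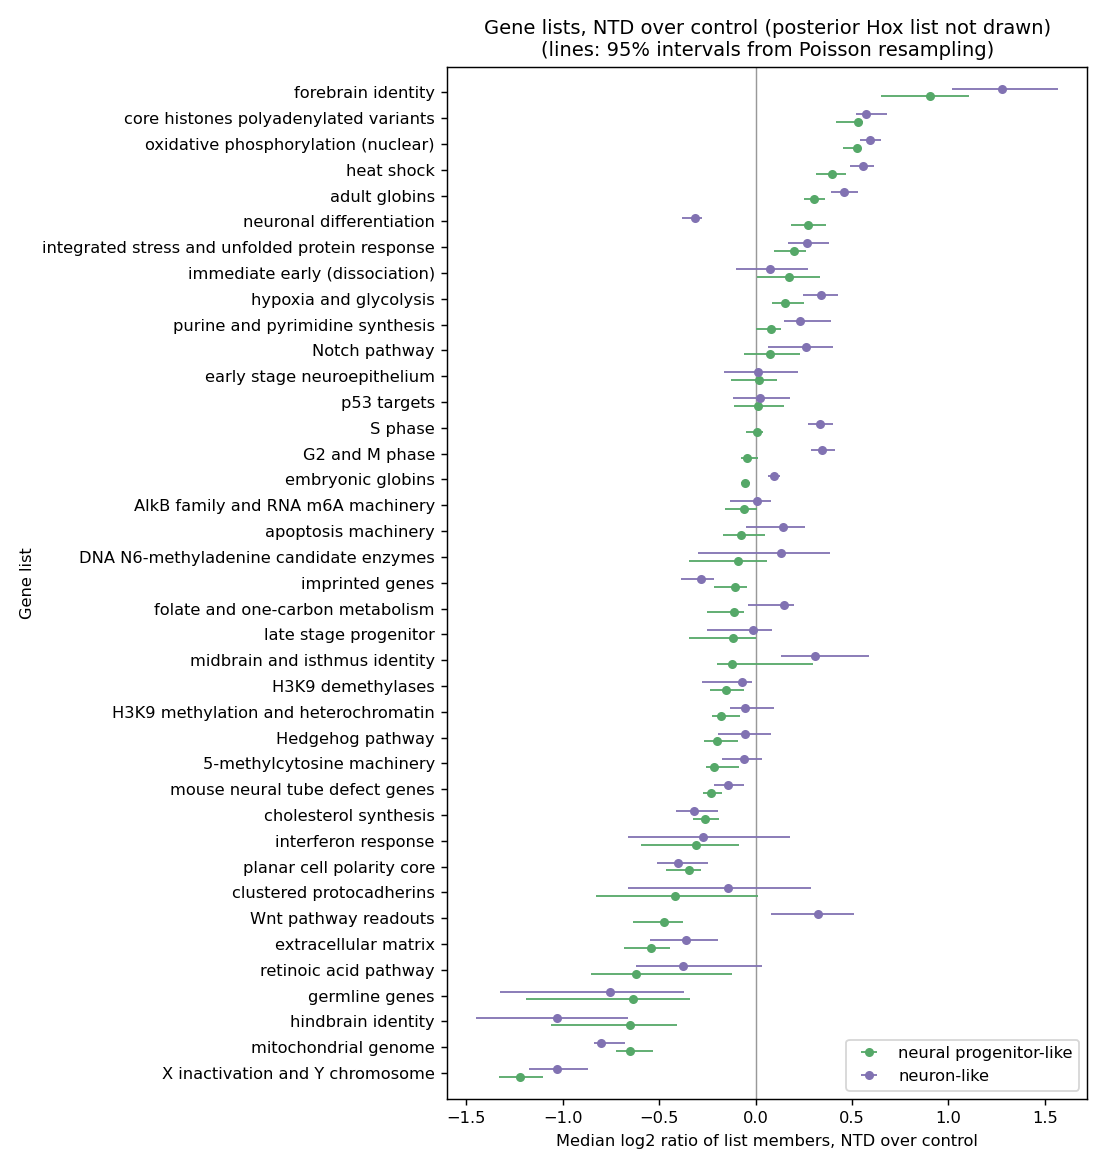
Median log2 ratio of NTD over control (x axis) of 39 gene lists (y axis) in neural progenitor-like and neuron-like cells, with 95% intervals from Poisson resampling. Forebrain identity was at 0.91 and 1.28 and the mitochondrial genome at -0.65 and -0.80, and all 17 progenitor-like medians from -0.23 to 0.02 and 13 of 14 neuron-like medians from -0.14 to 0.14 turned sign under at least 1 of 5 scalings.

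Sex-linked genes differed between the libraries. In progenitor-like cells Xist, the RNA that coats the inactive X chromosome, was at 964 CPM in the NTD library and 178 CPM in control, a log2 ratio of 2.44 (2.35 to 2.52). Tsix had 2.11 (1.94 to 2.28), and the Y chromosome gene Eif2s3y had -1.70 (-1.84 to -1.56). Of thinned cells, 4.63% of control and 40.9% of NTD cells held Xist without a Y chromosome gene, while 48.4% and 14.3% held a Y chromosome gene without Xist. Without thinning these shares were 3.93% and 42.4% for Xist alone and 53.1% and 18.6% for Y chromosome genes alone. Over all kept cells the highest genes were Xist at 3.26, Tsix at 2.94, Sfta3-ps, a leading gene of cluster 1, at 1.70, Hist1h2ae at 1.36 and Fabp7 at 1.33. Among Y-positive progenitor-like cells only, the Alkbh1 log2 ratio was -0.60.

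In progenitor-like cells log2 ratios were lower for genes of longer genomic span, with a Spearman correlation of -0.572 across 5040 genes, which are not independent replicates. The sixth of genes with the shortest spans had a median log2 ratio of 0.38 and the sixth with the longest spans one of -0.34. The correlation was below -0.2 in 15 of the 16 clusters tested, and -0.188 in cluster 0. Alkbh1 spans 18178 bp.

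**Figure D5:**
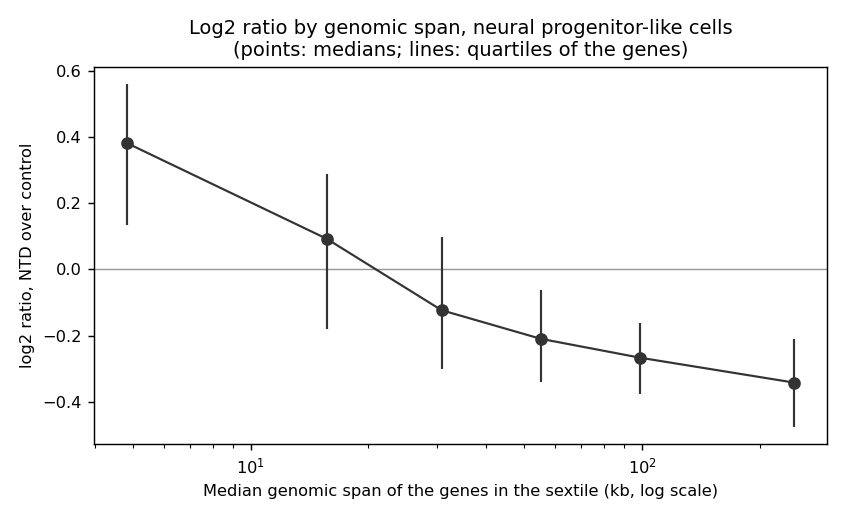
Log2 ratio of NTD over control (y axis) against median genomic span (x axis, log scale) for 6 equal groups of genes in neural progenitor-like cells, with points at medians and lines over the quartiles. The median was 0.38 for genes with a median span of 4843 bp and -0.34 for genes with one of 244677 bp.

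The comparison within neuron-like cells asked the same question of differentiated cells, with 1503 control cells and 2435 NTD cells. Alkbh1 was lower in the NTD library here too, at 73.3 CPM (67.2 to 79.9) from 528 UMIs against 109 CPM (99.997 to 119) from 498 UMIs in control, a log2 ratio of -0.58 (-0.76 to -0.40). The posterior Hox list had a median of -5.27 with all 24 measured members lower, and the forebrain list one of 1.28 (1.02 to 1.57) with 15 of 16 higher. Hoxc6 had a log2 ratio of -6.85 (-8.90 to -5.64) and Hoxa9 of -5.59 (-6.81 to -4.72), and Hoxd3os1 had 264 control UMIs and 1 NTD UMI. Dlx6os1, a forebrain interneuron transcript, was at 157 CPM against 59.3 CPM in control, a log2 ratio of 1.40 (1.21 to 1.60).

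The 10 lowest genes in neuron-like cells were Hox genes or their antisense transcripts, apart from Afp at -5.76 and Apoa1 at -5.45. The highest were Xist at 2.46 and Tsix at 2.05, then the histone genes Hist2h2ac, Hist1h2ae, Hist1h3c, Hist1h4d and Hist1h1b between 1.37 and 1.61, Myl7 at 1.44 and Fabp7 at 1.41. Neuronal differentiation genes had a median of -0.32 (-0.38 to -0.28) by totals and -0.09 relative to like span, with 15 of 31 lower and 3 higher in NTD neuron-like cells. S phase genes had a median of 0.33 (0.27 to 0.40), with 23 of 43 higher, and G2 and M phase genes one of 0.34 (0.29 to 0.41), with 29 of 54 higher. Notch pathway genes, which are expressed in progenitor-like cells, were also higher here, with a median of 0.26 (0.06 to 0.40) by totals and 0.42 with TMM scaling. Of 16 members 7 were higher and 2 lower, and transcripts from progenitor-like cells would raise all 3 lists. Planar cell polarity genes had a median of -0.40 (-0.51 to -0.25) by totals and -0.25 with TMM scaling. Wnt pathway readouts had one of 0.32 (0.08 to 0.51) by totals, 0.48 with TMM scaling, 0.51 relative to like span, 0.21 with cells weighted equally and 0.16 in thinned cells, where the interval held 0.

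Folate and one-carbon genes had a median of 0.15 (-0.04 to 0.20) by totals and 0.30 with TMM scaling in neuron-like cells, and H3K9 methylation and heterochromatin genes one of -0.06 by totals and 0.10 with TMM scaling. The median log2 ratio of all 14868 measured genes was -0.15 by totals and 0.00 with TMM scaling. Of the neuron-like clusters, cluster 4 held the most cells in both libraries, with 3.86% of control and 7.92% of NTD kept cells.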

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

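Of the tests below, those on free RNA were set before their results were seen, and those on trunk genes, globins, thinned cells, mitochondrial genes, genomic span and forebrain-positive cells were chosen only after the result was seen.

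For 3 gene lists the median log2 ratio lay on opposite sides of 0 in neural progenitor-like and neuron-like cells, with both intervals excluding 0, and the difference between the classes was not tested. Wnt pathway readouts were at -0.48 in progenitor-like cells and 0.32 in neuron-like cells. In neuron-like cells they were at 0.16 in thinned cells, with an interval that held 0, and 0.21 with cells weighted equally. There they were also at 0.48 with TMM scaling and 0.51 relative to genes of like span. Neuronal differentiation genes were at 0.27 in progenitor-like cells and -0.32 in neuron-like cells, where they were at -0.088 relative to genes of like span. Embryonic globins were at -0.054 in progenitor-like cells, where TMM scaling turned them positive, and at 0.093 in neuron-like cells, where they were -0.15 relative to genes of like span.

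Posterior Hox genes were lower in NTD progenitor-like cells, with a median log2 ratio of -5.15. A younger stage of the NTD embryos would give a lower adult share of globin UMIs in erythroid-like cells. That share was instead slightly higher, at 14.2% in 221 control cells and 16.3% in 156 NTD cells. The log2 ratio of adult over embryonic globin was 0.23. Without replicate libraries, so small a difference cannot be told apart from variation between embryos or in the tissue taken. It therefore cannot decide stage, which stays open. Loss of Hox transcripts alone, from posterior cells present in both libraries, would leave other trunk genes unchanged. Yet 10 of 12 non-Hox trunk and limb genes not seen before listing were also lower by the minimum fold used to count members. These genes were summed over all kept cells, so they cannot decide whether Hox transcripts were also lost within posterior neural cells. A candidate explanation that these genes leave open is more tissue from behind the head in the control library. Their median over all kept cells was -2.40. The abundant transcripts Afp and Apoa1 were at 237 and 89.5 CPM in control and 3.63 and 2.03 CPM in NTD. As markers of trophoblast, yolk sac or liver, Afp and Apoa1 do not show that the added tissue came from the trunk. However, Uncx and Nkx2-5 were not lower. Muscle-like cluster 23 held 0.322% of control and 0.342% of NTD kept cells. Its leading genes Ryr2 and Myh6, chosen after their values were seen, are heart genes, so such tissue was not in the control library alone. A loss of posterior tissue in the NTD embryos themselves also stays open, untested.

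Log2 ratios in progenitor-like cells were lower for genes of longer genomic span, with a correlation of -0.572 across genes. The correlation was -0.593 after cells were thinned to 1559 UMIs, with shallower cells left out. Thinning keeps the expected share of each gene within a cell, so this value could hardly move. It therefore cannot decide whether a difference in depth per cell played a part. More free RNA in NTD cells may account for the trend, but this stays open. The correlation given each gene's level in progenitor-like cells over cluster 0, the low-UMI cluster taken as nearest to free RNA, was 0.0335. That level itself correlated with span at 0.762 and shares control counts with the log2 ratio. A value near 0 therefore cannot single out free RNA among causes linked to span. More cytoplasm captured in NTD cells cannot be told apart from more free RNA, since the mitochondrial genome list was at -0.65 but mitochondrial UMIs were also lower in NTD cells of cluster 0, at 0.325% against 0.639%. No biological explanation was tested.

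Alkbh1 was lower in NTD progenitor-like cells, with a log2 ratio of -0.54 (-0.64 to -0.43). The trend with genomic span is argued against as the whole of this, since the 331 genes of like span and level had a median of 0.10, with Alkbh1 at their 2.72th percentile, and correcting for span alone left -0.40 (-0.50 to -0.29). Cells taken from other positions along the axis cannot be told apart, since Alkbh1 was at -0.41 (-0.73 to -0.06) from 84 control UMIs in progenitor-like cells with a forebrain UMI and no Hox UMI, where the 7 forebrain genes left out of that choice, at 0.33 (-0.69 to 0.77), do not show whether position was matched, and at -0.38 (-0.55 to -0.20) in those with no Hox UMI, where such genes were higher at 0.54 (0.13 to 0.88). Dilution by free RNA cannot be told apart either, since 538 genes with a like level over cluster 0 had a median of -0.33 and Alkbh1 stood at their 12.5th percentile. A lower Alkbh1 level after the treatment stays open, untested across embryos.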

How the results depend on the processing

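The matched UMI floor, doublets at the expected rate, equal weights for clusters, Y-positive cells, shares without clusters of 1 library or among neural cells only, and ratios relative to genes of like span were chosen only after the result was seen. No paired analysis was possible because each group had 1 library. Not filtering cells moved nothing, since the filter removed no barcode, and so says nothing about stability. Of the values that answer the comparisons, 110 stayed within their counting interval, 35 moved and 2 reversed, and of the other values 1848, 343 and 8 did. The cause was not tested for any of these unless given here.

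The progenitor-like share, 16.5 points higher in NTD, was 12.9 points higher with the stricter filter, 17.7 at resolution 0.5, 10.1 at resolution 2.0 and 13.9 with genes scaled within each library. It was 13.8 with doublets at the expected rate, 14.8 with the matched floor, 11.9 without clusters of 1 library and 10.7 among neural cells. The neuron-like share, 4.94 points higher, was 3.14 with the stricter filter, 2.64 with the matched floor, 2.18 without clusters of 1 library and reversed to -3.15 among neural cells. Among neural cells alone, neuron-like cells made up 31.6% in the control and 28.5% in the NTD library, and progenitor-like cells 52.9% and 63.6%. Both ways of taking the neuron-like share depend on which other cells are in the denominator. The share of all kept cells thus also depends on tissue found mostly in the control library. The mesenchyme-like share reversed to 8.05 without clusters of 1 library, because 2 of its 3 clusters were left out. The neuroblast-like share reversed to 0.651 with the stricter filter and to 0.755 with doublets kept.

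In progenitor-like cells TMM scaling moved every median by the same amount, to -0.35 for Alkbh1, 0.0064 for H3K9 methylation and heterochromatin, 0.070 for folate, -0.049 for neural tube defect genes, 0.20 for p53 targets, 0.19 for S phase, 0.14 for G2 and M phase and 0.45 for neuronal differentiation. It reversed embryonic globins to 0.13, as did the stricter filter to 0.079. Relative to genes of like span Alkbh1 was at -0.40, folate at 0.063, neural tube defect genes at 0.018, S phase at 0.15, G2 and M phase at 0.12 and neuronal differentiation at 0.54. That setting reversed H3K9 methylation and heterochromatin to 0.029, H3K9 demethylases to 0.13, the 5-methylcytosine machinery to 0.057 and embryonic globins in neuron-like cells to -0.15. With totals without mitochondrial, ribosomal protein and haemoglobin genes, folate was at -0.043, neural tube defect genes at -0.16, S phase at 0.078 and G2 and M phase at 0.024. G2 and M phase was at -0.10 with the stricter filter and -0.083 with the matched floor. Neural tube defect genes were at -0.15 with doublets kept and -0.29 in thinned cells. Neuronal differentiation was at 0.12 with doublets at the expected rate and 0.13 with clusters weighted equally.

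Counting intervals at this depth resolved Alkbh1 but not Alkbh4, N6amt1 or Mettl4, whose intervals held 0. They do not cover differences between embryos.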

Other observations

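No explanation was tested in this part, and its values were examined only after the main comparisons were seen.

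In neural progenitor-like cells cholesterol synthesis genes had a median log2 ratio of -0.26 (-0.32 to -0.19) for NTD over control by totals, -0.08 with TMM scaling and -0.10 relative to genes of like span, at the 10.9th percentile of matched lists, with 9 of 20 lower and 1 higher. Among them Lss had -0.74 (-1.01 to -0.47) and Dhcr7, which makes cholesterol in its last step, -0.47 (-0.73 to -0.20). Imprinted genes had a median of -0.10 by totals and 0.08 with TMM scaling, with 8 of 22 lower and 2 higher. Among them Igf2r had -1.12 (-1.26 to -0.97), Igf2 -0.94 (-1.11 to -0.76) and H19 -0.92 (-1.04 to -0.79). Germline genes silenced by DNA or H3K9 methylation were lower in 6 of 7 measured members and higher in 0, with a median of -0.63 (-1.19 to -0.34). Of 34 clustered protocadherins 8 were measured, with a median of -0.42 (-0.83 to 0.01) by totals and -0.13 relative to like span, and 9 interferon response genes had a median of -0.31 (-0.59 to -0.09) by totals, -0.13 with TMM scaling and -0.68 in thinned cells.

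Adult globins had a median of 0.30 (0.25 to 0.36) in progenitor-like cells and 0.46 (0.39 to 0.53) in neuron-like cells by totals, which were 0.20 and 0.22 relative to like span, while haemoglobin genes took 1.16% of progenitor-like UMIs in control and 1.24% in NTD. Both are erythroid transcripts found in cells that should lack them. Of thinned progenitor-like cells, 42.5% in control and 41.4% in NTD were called S phase, and 49.3% and 54.8% were called G2 or M phase. Without thinning these shares were 41.5% and 34.2% for S phase and 54.6% and 64.8% for G2 or M phase. Free RNA differed between the libraries, so these calls do not show a difference in cycling.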
